A study of Mus musculus with 2 samples.

How the data were processed

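Bone marrow cells of mice on the C57BL/6 background were profiled by droplet-based single-cell RNA sequencing with 10x Genomics 3′ chemistry. By label, both genotypes lacked Apoe, the apolipoprotein whose loss causes high plasma cholesterol and atherosclerosis in mice. The groups differed in Itgb3, which encodes integrin β3, and each group was 1 library from animals of 6 months. The library with the genotype Apoe(-/-) Itgb3(-/-) is called the null-labelled library, and that with Apoe(-/-) Itgb3(+/+) the control-labelled library. How many animals each library holds is not given in the sources used here.

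The deposited matrices held whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, without normalization. The submitters' processing notes name Cell Ranger 3.0, Seurat and the genome build mm10, and the software version per the file headers is 3.1.0. Filters applied before deposit beyond the matrix itself are not given in the sources used here, and no cell type annotation was used from the study. The features listed 31053 genes, of which 30934 (99.6%) had their Ensembl identifier in GENCODE vM21 for GRCm38 (mm10). Coordinates are from that annotation and count from 1.

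The null-labelled matrix held 4281 barcodes and 44694854 UMIs, and the control-labelled matrix 12764 barcodes and 79192158 UMIs. Barcodes with under 200 genes or over 10% mitochondrial UMIs were left out, which removed 1307 (30.5%) and 3479 (27.3%) barcodes. Scrublet, as implemented in scanpy, scored doublets within each library, and the highest scores were removed at an expected rate of 0.8% per 1000 cells, which took out 71 cells (2.39%) of the null-labelled and 690 cells (7.43%) of the control-labelled library. Its automatic threshold would have marked 13 and 375 cells. The cells kept numbered 2903 with 33570111 UMIs and 8595 with 59003767 UMIs.

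Counts per cell were scaled to 10000, log-transformed, and reduced to 30 principal components of 2000 variable genes, leaving out mitochondrial, ribosomal, hemoglobin, immunoglobulin and sex-linked marker genes as well as Malat1, Gm42418 and Itgb3. Both libraries were clustered jointly without integration, by Leiden clustering at resolution 1 on a graph of 15 neighbours, and clusters of 60 or more cells were split again at resolution 0.5. This gave 27 clusters and 112 sub-clusters. Sub-clusters were named from marker genes of 19 classes, of which 16 were assigned. A sub-cluster stayed unnamed with under 3 detected markers, with more markers of another class than of its own among its 10 leading genes, or with a median UMI count far under that of its library and no own marker there. The scores behind the names, including a detection minimum of 10% of cells and an offset of 20 CPM, were set after the data were seen. Sub-clusters with markers of both stages of the neutrophil or B lineage were kept in the lineage without a stage. Of the 112 sub-clusters, 105 drew 90% or more of their cells from 1 library, so a sub-cluster can stand for a library rather than a cell type, and the names are rebuilt here.

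Shares of cells per class carry exact Clopper-Pearson 95% intervals. Within each class having at least 100 cells in both libraries, of which there were 7, and over all cells, UMIs were summed per library and expressed as CPM, the count divided by the total of the class in that library and scaled as counts per 1e6. Sums carry exact Poisson intervals, and ratios of CPM carry an exact interval from the split of the UMIs between the libraries. With 1 library per genotype no test between genotypes was possible, so no p-value is given, and every interval covers counting error only. Genes at 2-fold or more were counted by size among genes with at least 50 CPM in either library and 30 UMIs over both. Where a library had 0 UMIs, a fold is given against a floor of 3 UMIs in that library as a lower bound.

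Named genes were chosen by the bound of the ratio's interval nearest to 1: the 12 highest and 12 lowest in the 3 classes with the most cells in their smaller library, and the 5 highest and 5 lowest in the other classes and over all cells. Predicted genes, immunoglobulin segments and sex-linked markers were left out of that ranking. Itgb3, Apoe, Itga2b and Itgav were always reported. A few genes that this rule named are not reported here. For each gene list, the 2 members with the highest CPM and the 2 with the largest ratio were also named as examples. The design, markers, gene lists, rule for named genes and processing alternatives were fixed before the data were examined.

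The 26 gene lists were integrins, interferon response, MHC class II, NF-kB and inflammatory cytokines, TNF and TGF-beta pathway, primary granules, secondary granules, S100 and late neutrophil genes, cholesterol efflux and LXR targets, cholesterol synthesis and uptake, scavenger receptors, clonal hematopoiesis genes, immediate early and dissociation genes, heat shock, mitochondrially encoded genes, ribosomal proteins, hemoglobin, platelet and megakaryocyte genes, osteoclast genes, G2M and mitosis, DNA replication, glycolysis, antioxidant and iron genes, chemokine receptors and retention, classical against nonclassical monocyte genes, and light chain and B activation. The ribosomal list was defined by symbol and therefore also holds S6 kinase genes such as Rps6ka2. A list was summarised by the median log2 ratio, null-labelled over control-labelled, of members with 30 or more UMIs, using a prior of 0.5 UMI and needing 3 measured members, and by the percentile of that median among 10000 random lists of the same size matched on expression. Values relative to all genes take off the median of all genes with 30 or more UMIs in the class, whereas the medians given with the numbers of genes at 2-fold are over the genes that also pass the CPM minimum. Class markers made up 1 member of the interferon list, 2 of MHC class II, 5 of primary granules, 8 of secondary granules, 6 of the S100 list, 9 of the platelet list, 5 of the monocyte list, 6 of the osteoclast list, 3 of hemoglobin, 5 of chemokine receptors, 2 of integrins, 1 of scavenger receptors and 1 of the antioxidant list, and 0 of the others. Those lists partly define the classes they describe.

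Cells with list UMIs and cycling cells, which hold 3 or more UMIs of the G2M list, were counted after every cell was thinned to 1000 UMIs, leaving out shallower cells. Free RNA, released by broken cells into the suspension, was estimated per library from hemoglobin and neutrophil genes in B and T cells. Their level there was 6.05% of the all-cell level for hemoglobin and 0.277% for neutrophil genes in the null-labelled library, and 27.6% and 0.892% in the control-labelled library. The subtraction used the pooled 3.88% and 14.7%, with counts under 0 set to 0. A gene at 0 in both libraries then takes a ratio set by the class totals and the prior. The sources disagree, and 97.2% of the hemoglobin UMIs of control-labelled T-like cells lay in 21 cells, which evenly spread free RNA would not give. The amount subtracted is therefore uncertain and may be too large in the control-labelled library.

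The alternatives were no cell filter, at least 500 genes, at most 5% mitochondrial UMIs, no doublet removal, halved and doubled clustering resolution, each library clustered on its own, thinning before clustering, TMM factors from edgeR 4.0.16 in R 4.3.3, totals without the 20 most abundant genes, means over cells, free RNA subtraction, other minimums of CPM or UMIs, and other settings of the cycling share. Clustering and naming without the 106 genes that differed 2-fold or more in the same direction in 5 or more classes was added after the data were seen. The functions were tested on simulated counts with 200 genes changed per comparison. All simulated 4-fold genes that passed the minimums were recovered in every comparison (100%), and a list shifted by 2 on the log2 scale came back at 1.96 in erythroid cells, run on 1727 genes, and at 1.99 in B precursors, run on 3103 genes. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.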

Results

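Bone marrow cells of mice labelled Apoe(-/-), a genotype used as a model of atherosclerosis, were profiled at 6 months of age in 1 library with the genotype label Itgb3(-/-) and 1 library with Itgb3(+/+). The comparison asks how the cellular makeup and the transcripts of the marrow differ between the null-labelled and the control-labelled library. After filtering, the null-labelled library held 2903 cells with 33570111 UMIs and a median of 9321 UMIs and 1807 genes per cell. The control-labelled library held 8595 cells with 59003767 UMIs and a median of 4812 UMIs and 1188 genes per cell. Depth per cell therefore differed between the libraries, and class shares below were measured across that gap. There are no replicates, so every difference is between 2 libraries and every 95% interval covers counting error only.

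Itgb3 encodes integrin β3, which pairs with Itga2b on platelets and with Itgav on other cells (ENSMUSG00000020689, chromosome 11 from 104608000 to 104670476 on the plus strand, mm10, GENCODE vM21). Its transcripts were present in both libraries. Over all cells, 248 UMIs in the null-labelled library gave 7.39 CPM (95% interval 6.50 to 8.37), and 1391 UMIs in the control-labelled library gave 23.6 CPM (22.4 to 24.8), a value 3.19-fold lower in the null-labelled library (2.79 to 3.67). Of the control-labelled UMIs, 861 came from 13 megakaryocyte-like cells, and without that class Itgb3 was at 7.18 CPM and 9.01 CPM, 1.25-fold lower (1.08 to 1.47). Those 13 cells held 159719 UMIs of all genes at a median of 841, so a few deep cells dominate that class. As a mean over cells, the Itgb3 log2 ratio of -1.67 became -0.65. Which part of the gene the null allele lacks is not given in the sources used here, and a count from 3′ ends outside the deleted part checks nothing, so the genotype stands as a label.

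Megakaryocyte-like cells, the platelet-producing class, held Itgb3 at 5391 CPM in the control-labelled library, and the null-labelled library had 2 such cells with 7 UMIs (2058 CPM). Immature neutrophil-like cells held Itgb3 at 8.59 CPM in the null-labelled and 19.9 CPM in the control-labelled library, 2.31-fold lower (1.702 to 3.20), and monocyte-like cells held 1 UMI against 55 UMIs, a ratio of 24.1 (4.14 to 967). Values were higher in the null-labelled library in hematopoietic stem and progenitor-like (HSPC-like) cells, with 70 UMIs at 38.9 CPM (30.3 to 49.1) in the null-labelled and 15 UMIs at 12.3 CPM (6.87 to 20.2) in the control-labelled library, 3.17-fold higher (1.80 to 5.96). These cells lay in different sub-clusters, with 39 null-labelled cells in sub-cluster 14 and 24 in sub-cluster 23, which had Itga2b among its leading genes and the megakaryocyte as its second class, and 81 of 85 control-labelled cells in sub-cluster 22. Within sub-cluster 23, 48 UMIs in 24 cells stood against 3 UMIs in 4 cells, a ratio of 1.56 (0.504 to 7.85), so no order within 1 type of HSPC-like cell is read. In mature neutrophil-like cells the values were 23.7 CPM and 17.6 CPM, with a ratio whose interval spanned 1 (0.875 to 2.05). B-like and T-like cells, in which the gene should be low, held 7.38 CPM (5.32 to 9.98) in the null-labelled library. With each cell thinned to 1000 UMIs, 4 of 67 HSPC-like cells (5.97%) and 7 of 809 B-like and T-like cells (0.865%) of the null-labelled library held an Itgb3 UMI, against 29 of 67 and 39 of 812 cells unthinned, at median depths of 21338 and 5624 UMIs. In the control-labelled library the thinned counts were 0 of 85 HSPC-like cells and 1.12% of B-like and T-like cells, so its HSPC-like share was not above background.

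The other genes of the design were also detected. Itga2b, the partner of integrin β3 on platelets, was at 9.35 CPM and 23.4 CPM over all cells, 2.499-fold lower in the null-labelled library (2.21 to 2.83). Itgav, its other partner, was 1.54-fold higher (1.36 to 1.75), at 14.2 CPM and 9.20 CPM. Apoe (ENSMUSG00000002985, chromosome 7 from 19696109 to 19699188 on the minus strand), lacking by label in both genotypes, was counted at 62.0 CPM and 98.4 CPM, 1.59-fold lower (1.51 to 1.67), and the same limit of 3′ counting applies.

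The marrow of the null-labelled library held relatively fewer neutrophil-like and more erythroid-like cells. The neutrophil lineage, short-lived phagocytes made in the marrow, was 21.5% of its cells (95% interval 20.05 to 23.1) and 33.3% of the control-labelled cells (32.3 to 34.3), a ratio of 0.647 (0.593 to 0.706). Mature neutrophil-like cells were 7.54% and 15.2% (ratio 0.496, 0.428 to 0.572), with a log2 ratio from -2.31 to -0.97 over the alternatives, whereas immature neutrophil-like cells were 14.0% and 14.6% with an interval that spanned 1 (0.856 to 1.07). Erythroid-like cells, the red cell precursors, were 33.3% and 23.8% (ratio 1.40, 1.30 to 1.51). The erythroid share depended on the cell filter, with a log2 ratio of 0.21 without filter against 0.49 with it.

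B lineage-like cells were 23.4% and 21.8% of cells, with a ratio interval spanning 1 (0.980 to 1.17), but their stages differed. B precursor-like cells were 4.99% and 12.2% (ratio 0.408, 0.341 to 0.486), and mature B-like cells 13.3% and 9.60% (1.39, 1.22 to 1.57). Both stages reversed when cells with over 5% mitochondrial UMIs were left out, to log2 ratios of 0.28 for B precursors and -5.45 for mature B cells, so no order of the stages is read. T-like cells were 4.58% and 2.37% (1.93, 1.54 to 2.41), and monocyte-like cells 3.96% and 5.92% (0.669, 0.542 to 0.820). Granulocyte-monocyte progenitor-like cells were 3.41% and 4.15%, with an interval spanning 1 (0.650 to 1.03). HSPC-like cells were 2.31% and 0.989% (2.33, 1.67 to 3.25), a share not run under the alternatives. Their null-labelled cells were mostly in sub-clusters 14, with 39 against 0 control-labelled cells, and 23, with 24 against 4. Sub-cluster 22, with the HSPC markers Hlf and Meis1 among its leading genes, held 4 against 81, so no expansion of stem cells is read. Plasma-like cells, named after the cells that secrete antibody, numbered 28 and 2. Of the 28, only 8 held a UMI of Jchain and 4 a UMI of Igha, the leading genes, so no number of antibody-secreting cells is read. Unnamed cells made up 1.48% and 3.99%, B cells without a stage 5.10% and 0.0116%, and neutrophils without a stage 3.47% of the control-labelled library against 0 of 2903 cells, which allows up to 0.127%. Median UMIs per cell were higher in the null-labelled library in each of the 7 compared classes, for example 7108 against 2436 in mature neutrophil-like and 10023 against 5784.5 in erythroid-like cells.

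**Figure D1:**
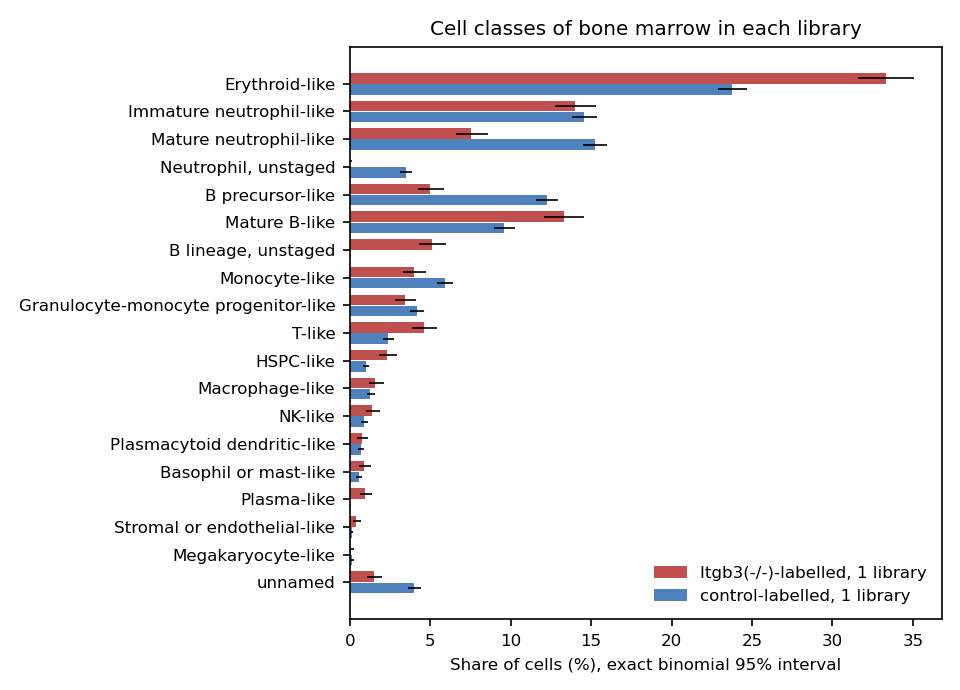
Share of cells in percent, one pair of bars per cell class for the null-labelled and control-labelled libraries, with exact binomial 95% intervals. Erythroid-like cells were 33.3% against 23.8% and mature neutrophil-like cells 7.54% against 15.2%.

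Interferon-response genes were higher in the null-labelled library in every class compared. This list of 18 genes holds transcripts that interferons induce, such as Isg15, the Ifit genes, guanylate-binding proteins and the chemokine Cxcl10. In erythroid-like, immature neutrophil-like and B precursor-like cells, 18 of 18 members were 2-fold or more higher. In monocyte-like cells it was 17 of 18, and in mature B-like, mature neutrophil-like and T-like cells 16 of 18, with 0 members 2-fold lower in any of them. The median log2 ratio ran from 2.38 in T-like cells (2.04 to 2.68) to 4.93 in immature neutrophil-like cells (4.74 to 5.25), and its percentile among 10000 random lists was 100% in each of the 7 classes. Free RNA subtraction moved the highest of these medians to 6.75 and the limit of 5% mitochondrial UMIs the lowest to 1.99.

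Isg15, a ubiquitin-like protein (ENSMUSG00000035692, chromosome 4 from 156199424 to 156200818), was at 2311 CPM and 127 CPM over all cells, 18.1-fold higher. Cxcl10 (ENSMUSG00000034855, chromosome 5 from 92346638 to 92348889) was 302-fold higher, Gbp2 (ENSMUSG00000028270, chromosome 3 from 142620602 to 142638008) 125-fold, and Ifitm3, which restricts virus entry, 6.61-fold. Relative to the median of all genes, here every gene with 30 or more UMIs in the class, the list lay higher by 5.55 in erythroid-like, 5.05 in immature neutrophil-like, 4.97 in B precursor-like, 4.15 in monocyte-like, 3.53 in mature neutrophil-like, 3.13 in mature B-like and 2.41 in T-like cells.

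Cell by cell, after thinning to 1000 UMIs, 84.6% of the cells of the null-labelled library (83.2 to 85.9) held 3 or more UMIs of the list, against 21.5% of the control-labelled cells (20.6 to 22.4). Unthinned, the shares were 98.6% and 64.4%, and 69 and 193 shallower cells were left out. The thinned shares were 91.7% and 14.1% in erythroid-like, 98.8% and 12.8% in immature neutrophil-like, 100% and 42.4% in mature neutrophil-like, 100% and 76.2% in monocyte-like, 69.9% and 9.03% in B precursor-like, 62.9% and 9.75% in mature B-like, and 42.9% and 4.46% in T-like cells. No class without these genes was defined, and T-like cells were the lowest class in both libraries.

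**Figure D2:**
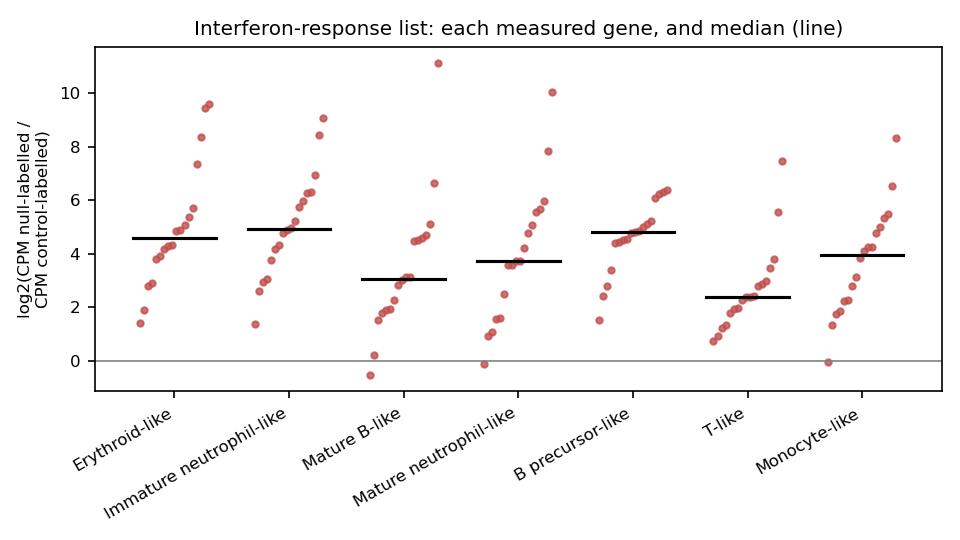
Log2 ratio of CPM, null-labelled over control-labelled, for each measured interferon-response gene as a point, with the list median as a line, per cell class. The medians lie between 2.38 in T-like and 4.93 in immature neutrophil-like cells.

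Over all cells, Saa3, Jchain and the chemokines Cxcl10 and Cxcl9 were among the genes furthest higher, and Ly6g, Ccl6 and Lyz2 among those furthest lower. Saa3, an acute-phase serum amyloid A (ENSMUSG00000040026, chromosome 7 from 46711998 to 46715700), was at 2629 CPM against 0.254 CPM, 10342-fold higher (6269.8 to 18478). Jchain, which joins secreted antibodies, was 954-fold higher, with 12420 of its 12484 UMIs in 8 plasma-like cells, Cxcl9 (ENSMUSG00000029417, chromosome 5 from 92321347 to 92328079) 277-fold and the immunity-related GTPase Iigp1 205-fold. Ly6g, the neutrophil surface marker (ENSMUSG00000022582, chromosome 15 from 75155240 to 75159126), was at 9.83 CPM against 214 CPM, 21.8-fold lower (19.6 to 24.4). Hacd4 was 18.7-fold lower, the chemokine Ccl6 13.1-fold, lysozyme Lyz2 (ENSMUSG00000069516, chromosome 10 from 117277331 to 117282321) 10.9-fold and Retnlg 10.0-fold. Of 2717 genes with enough counts, 214 were 2-fold or more higher and 329 lower, or 276 and 200 with TMM factors, which moved the median of these genes from -0.24 to -0.02. These sums over all cells also carry the different class shares.

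Gene lists over all cells are given relative to the median of all genes, with the percentile among random lists. NF-kB and inflammatory cytokine genes lay 1.83 above it (100%), with 12 of 17 members 2-fold higher, including Sod2 at 5.78-fold, the lipopolysaccharide receptor Cd14 at 12.3-fold and the chemokine Ccl2 at 27.2-fold. MHC class II genes, which present antigen, lay 0.85 above (99.8%), with 4 of 8 higher, such as Cd74 at 2.39-fold. Immediate early genes lay 0.68 above (99.8%) with Atf3 6.10-fold higher and Fosb 3.29-fold lower. Light chain and B activation genes lay 0.96 above (99.96%) with 4 of 9 higher, such as Bcl2a1b at 14.6-fold. Ribosomal protein genes lay 0.26 above (99.9%) with 87 of 89 within 2-fold. The 2 lower were not ribosomal proteins of most cells, being Rpl39l, with 0 UMIs against 30 and thus at least 5.69-fold lower, and the kinase Rps6ka2 at 4.79-fold lower.

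Platelet and megakaryocyte genes lay at -3.19 (percentile 0), with 13 of 14 lower, such as Ppbp at 42.2-fold and Pf4 at 10.7-fold, beside 2 and 13 megakaryocyte-like cells. Their log2 ratio of -3.43 became -0.84 as a mean over cells and -0.69 with thinning before clustering. Integrin genes lay at -1.03 (percentile 0), with 10 of 18 lower and 0 higher, such as Itga1 at 17.2-fold and talin, Tln1, at 2.49-fold lower. Monocyte subset genes lay at -1.35 (percentile 0) with 7 of 12 lower, primary granule genes at -1.04 (0.0300%) with 5 of 5 lower, such as Mpo at 3.05-fold, and secondary granule genes at -0.49 (0.330%) with 3 of 10 lower. DNA replication genes lay at -0.73 (percentile 0) with 7 of 16 lower, such as Rrm2 at 2.99-fold, and G2M genes at -0.25 (2.20%) with Top2a 2.21-fold lower. Chemokine receptor genes lay at -0.53 (0.770%) with 5 of 11 lower, such as Cx3cr1 at 13.3-fold and Ccr2 at 4.07-fold. Scavenger receptors lay at -0.61 (2.35%) with 4 of 10 lower, such as Trem2 at 4.18-fold.

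The remaining lists lay between the 5th and the 96th percentile. Cholesterol synthesis and uptake genes lay at -0.39 (6.17%) with 5 of 13 lower, such as Sqle at 3.53-fold. Cholesterol efflux genes lay at 0.18 (75.3%), with Plin2, a lipid droplet protein, 2.89-fold higher. Clonal hematopoiesis genes lay at 0.14 (65.2%) with Jak2 at 2.25-fold and Tet2 at 2.18-fold higher. The TNF and TGF-beta list lay at 0.34 (91.7%) with Thbs1 2.26-fold higher, glycolysis at 0.34 (94.6%) with Pfkfb3 2.12-fold higher, hemoglobin at 0.65 (93.5%) with Hbb-bs 1.34-fold higher, and osteoclast genes at 0.76 (95.1%) with Tnfrsf11a 3.89-fold higher and Acp5 2.35-fold lower. S100 and late neutrophil genes lay at 0.03 (49.4%) with Il1r2 12.1-fold higher, heat shock genes at -0.07 (30.2%) with Hsph1 5.18-fold lower, antioxidant genes at -0.07 (27.6%) with Hmox1 2.601-fold higher, and the 13 mitochondrially encoded genes at -0.21 (5.16%), all within 2-fold.

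**Figure D3:**
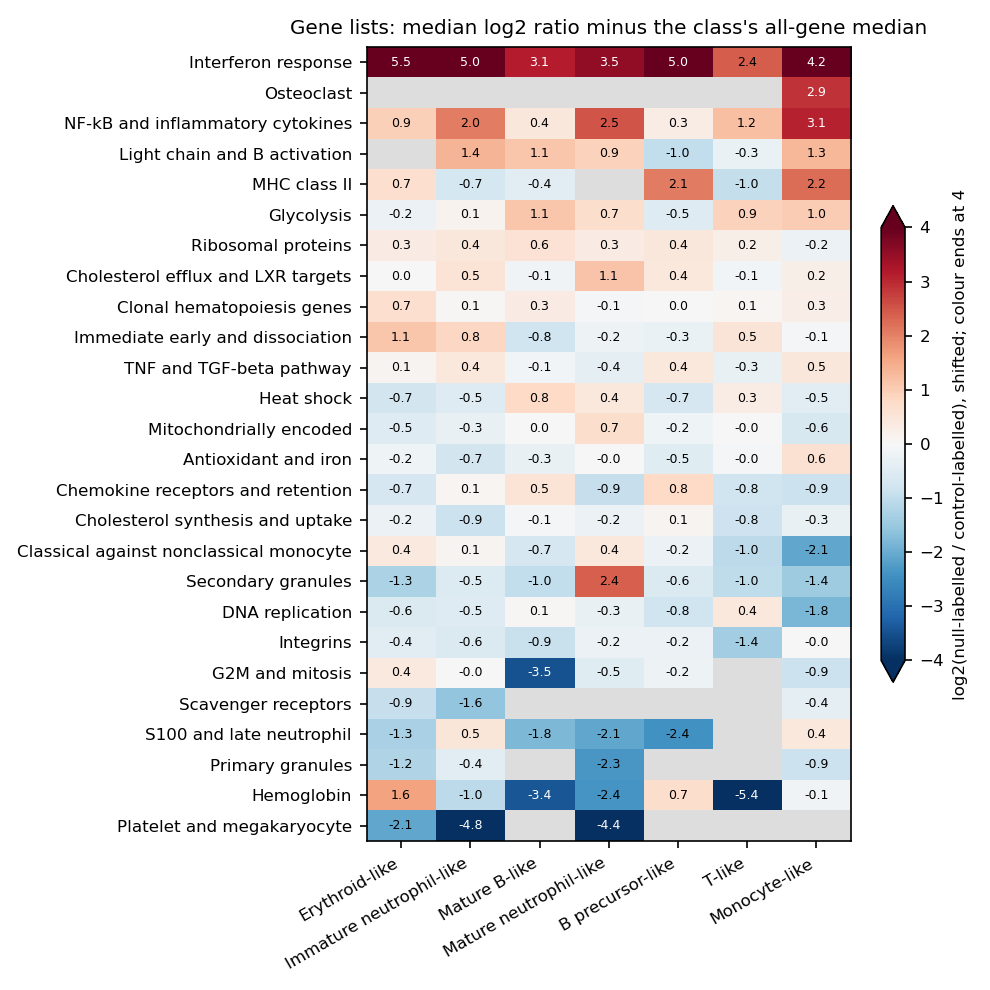
Heat map of the median log2 ratio of each gene list, null-labelled over control-labelled and relative to the median of all genes, in 7 cell classes, with the colour scale ending at 4. Interferon response and NF-kB genes lie above the median of all genes in each class, the former from 2.41 in T-like to 5.55 in erythroid-like cells.

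In erythroid-like cells, interferon-response transcripts were higher in the null-labelled library, and genes of DNA replication, heat shock and mitochondria were lower relative to all genes. Isg15 was at 5960.4 CPM against 327 CPM, 18.2-fold higher (17.7 to 18.7), and Ifitm3 was 33.6-fold higher. Gbp2 had 2589 UMIs against 5, 842-fold higher (360.4 to 2596). With 1 to 3 control UMIs, the ratios were 937 for Iigp1 (259 to 7745), 694 for Cd274, which encodes the checkpoint ligand PD-L1 (237 to 3369), and 1052 for the nucleic acid sensor Zbp1 (188 to 41627). Ifit3 (ENSMUSG00000074896, chromosome 19 from 34583531 to 34588731) was 373-fold, Gbp3 183-fold, Cxcl10 169.5-fold, Tor3a 67.9-fold, H2-T22 64.2-fold, Ddx58, which encodes the RNA sensor RIG-I, 54.3-fold, Ifit1 (ENSMUSG00000034459, chromosome 19 from 34640871 to 34650009) 52.0-fold and Trafd1 46.4-fold higher.

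The lowest genes of erythroid-like cells were Herc2, 13.5-fold lower (10.2 to 18.2), Fam162a at 12.7-fold, the red cell gene Smim1 at 11.6-fold, Ift140 at 11.3-fold, Ppid at 10.5-fold and the transcription factor Lyl1 at 10.0-fold. Nudt5, Coa3, the histone methyltransferase Ezh2, Josd2, Chac2 and Mns1 were between 9.70-fold and 7.80-fold lower, with Ezh2 at 21.8 CPM against 200.1 CPM. DNA replication genes were 2-fold lower in 14 of 16 cases and lay at -0.58 relative to all genes (0.170%), such as Dut at 5.18-fold and Rrm2 at 3.24-fold lower. Heat shock genes lay at -0.75 (0.450%) with 6 of 7 lower, such as Hsph1 at 17.2-fold, and mitochondrially encoded genes at -0.52 (0.190%) with 9 of 13 lower, such as mt-Nd2 at 4.37-fold. The log2 ratios of the 3 lists were -1.55, -1.72 and -1.49, and with TMM factors -0.69, -0.85 and -0.63, with 3 of 16, 3 of 7 and 4 of 13 genes 2-fold lower. Hemoglobin lay at 1.62 (98.2%) with 4 of 4 within 2-fold, such as Hba-a1 at 1.72-fold and Hbb-bs at 1.58-fold higher, and with TMM factors 4 of 4 were 2-fold higher at a log2 ratio of 1.51. Immediate early genes lay at 1.12 (99.7%) with 3 of 11 higher, such as Egr1 at 6.14-fold. Neutrophil transcripts were also lower, with secondary granule genes at -1.25 (0.0800%) and S100 genes at -1.30 (0.390%). With free RNA subtracted, both lists came to the same log2 ratio of 0.57, the value of genes set to 0 in both libraries. No change of sign is read from it. That subtraction used a share of 14.7% in the control-labelled library, which pools 27.6% from hemoglobin with 0.892% from neutrophil genes. Platelet genes lay at -2.08 (0.0200%).

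Of 2208 erythroid genes with enough counts, 163 were 2-fold or more higher and 1031 lower. That split depended on the scaling, and was 456 and 208 with TMM factors and 480 and 753 with the 20 most abundant genes left out. The median of these genes moved from -0.91 to 0.17 and -0.28. The class was spread over 29 sub-clusters. The largest in the null-labelled library were 37 and 34, of which 34 had among its leading genes Ifit1bl1, Ifit3b, Ifit1 and Rsad2. The largest in the control-labelled library were 57 and 60, of which 60 had Rrm2 and Klf1 among its leading genes. Interferon genes were also among the leading genes of smaller control-labelled sub-clusters, with Rsad2 in 66 and 67 and Isg15 in 4. The stages of maturation were not matched, so DNA replication and Rrm2 are not compared within 1 stage.

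Immature neutrophil-like cells of the null-labelled library held more interferon and NF-kB transcripts. Saa3 had 8802 UMIs against 1, a ratio of 15431 (2769 to 609545), and Ifit3 492 UMIs against 2, a ratio of 431 (119 to 3571). Gbp2 was at 587 CPM against 1.04 CPM, 566-fold higher (316 to 1135). Pla2g7, AW112010, Cxcl10, Ifit1, Zbp1, Slfn5, Xaf1, Upp1 and Bst2, which tethers virus particles, were between 192-fold and 53.6-fold higher. Ly6g was at 28.1 CPM against 810.3 CPM, 28.9-fold lower (24.8 to 33.8), and Lyz2 at 763 CPM against 11019.6 CPM, 14.4-fold lower (14.0 to 14.9). Ear2 was 17.1-fold, Hacd4 15.1-fold, Tnfsf13b, which encodes the B cell survival factor BAFF, 12.7-fold and Clec12a 8.997-fold lower. Zmpste24, the collagenase Mmp8, Hk3, Ly75, Cpne3 and Gca were between 8.77-fold and 6.76-fold lower.

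NF-kB and cytokine genes of immature neutrophil-like cells lay 2.04 above the median of all genes (100%), with 7 of 10 higher, such as Icam1 at 15.03-fold, Cd14 at 11.7-fold and Sod2 at 7.91-fold. Secondary granule genes lay at -0.53 (0.410%) with 4 of 10 lower and 2 higher, although the most abundant, Ngp, was 1.61-fold higher and Camp 1.57-fold lower. S100 and late neutrophil genes lay at 0.48 (96.2%) with 5 of 12 higher, such as Wfdc17 at 37.5-fold. Cholesterol synthesis genes lay at -0.86 (0.280%) with 5 of 10 lower, such as Msmo1 at 3.81-fold, antioxidant genes at -0.73 (0.160%), DNA replication at -0.53 (0.580%) and integrins at -0.58 (0.550%), among which Itgb7 was 49.4-fold higher. Ribosomal protein genes lay at 0.45 and immediate early genes at 0.82, with percentiles of 99.99% and 99.94%. Hemoglobin from other cells lay at -1.04 (0.2%), a sign that turned at a minimum of 500 genes. Of 2016 genes, 219 were higher and 243 lower, or 239 and 198 with TMM factors and 356 and 485 without the 20 most abundant genes. Sub-clusters 10, 13 and 11 held the class in the null-labelled library, and 81, 79, 82 and 100 held most of it in the control-labelled library. For the mature stage, 10, 13 and 11 scored 0.443, 0.587 and 0.418, and 81, 79, 82 and 100 scored 0.214, 0.478, 0.326 and 0.176. Ly6g and Mmp8 were among the leading genes of 79. The stages were not matched, so genes such as Ly6g and Mmp8 are not read as differences at a matched stage.

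Mature neutrophil-like cells of the null-labelled library held more interferon, NF-kB and secondary granule transcripts, and fewer of the S100 and late neutrophil list. Saa3 had 1537 UMIs against 0, at least 1127-fold higher, and Orm1, another acute-phase gene, was at 2207 CPM against 1.13 CPM, 1945-fold higher (759 to 7142). AW112010 was 413-fold higher, Cxcl10 had a ratio of 1327 over 2 control UMIs (367 to 10970.3) and the lipase Lipg a ratio of 917 over 1 UMI (164 to 36303). Ccl6 was at 26.2 CPM against 2517 CPM, 96.1-fold lower (71.0 to 133), and the adhesion gene Jaml 73.9-fold lower. BC100530, Dck and Mpzl3 had 0 UMIs in the null-labelled library and were at least 89.3-fold, 67.3-fold and 36.4-fold lower. Secondary granule genes lay 2.38 above the median of all genes (100%) with 6 of 10 higher, such as Chil3 at 69.4-fold, Ngp at 12.3-fold and Lcn2 at 6.64-fold. S100 and late neutrophil genes lay at -2.07 (percentile 0) with 7 of 12 lower, while S100a9, the most abundant, was 1.32-fold lower. The cells compared were not at 1 stage, since the null-labelled sub-clusters 9 and 12 scored 0.620 and 0.767 for the immature stage, the control-labelled sub-clusters 76 and 77 scored 0.273 and 0.173, and the mixed control-labelled sub-cluster 93 with 298 cells was left without a stage, so no difference within mature neutrophils is read.

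NF-kB and cytokine genes of mature neutrophil-like cells lay at 2.52 (100%), with 9 of 14 higher, such as Cd14 at 41.7-fold, Sod2 at 33.2-fold and Cxcl2 at 10.4-fold. Cholesterol efflux genes lay at 1.15 (98.1%), with 4 of 6 higher, such as the transporter Abca1 at 9.53-fold, and 2 lower, such as Abcg1 at 3.39-fold. Glycolysis lay at 0.69 (97.7%), with Tpi1 6.32-fold and Pgam1 4.01-fold higher. Cxcr2, the receptor for neutrophil-attracting chemokines, was 3.99-fold lower. Hemoglobin lay at -2.37 (0.0700%), a sign that turned when cells were thinned before clustering. Of 2381 genes, 538 were higher and 401 lower, or 345 and 688 with TMM factors, under which the median of these genes moved from 0.09 to -0.38. The null-labelled cells were in sub-clusters 9, with Cxcl2, Cd14 and Il1b among its leading genes, and 12, and the control-labelled cells in 77, also with Il1b, 76, 92, 94 and 78.

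Monocyte-like cells of the null-labelled library held more interferon, NF-kB and MHC class II transcripts and fewer of the monocyte subset list. Saa3 was at 31119 CPM against 1.32 CPM, 23583-fold higher (10834 to 64264), and the chemokine Ccl5 at 7349 CPM against 7.48 CPM, 983-fold higher (703 to 1419.6). AA467197 was 1205-fold higher, Sdc4 had a ratio of 2925 over 1 control UMI (524 to 115617), and Ccl12 with 818 UMIs against 0 was at least 624-fold higher. Cx3cr1, the fractalkine receptor of nonclassical monocytes, had 1 UMI against 493, a ratio of 216 lower (38.5 to 8532), AI839979 had 3 against 814, a ratio of 119 (40.5 to 577), and Cbfa2t3 had 2 against 447, a ratio of 97.7 (26.9 to 809). Stxbp6 and Klrb1f had 0 UMIs and were at least 50.3-fold and 37.0-fold lower.

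Relative to all genes, NF-kB and cytokine genes of monocyte-like cells lay at 3.08 (100%) with 10 of 14 higher, such as Il1b at 72.0-fold, Cxcl2 at 33.9-fold and Sod2 at 33.5-fold. MHC class II genes lay at 2.22 (99.97%) with 4 of 6 higher, such as H2-Aa at 5.48-fold and Cd74 at 3.74-fold, and their log2 ratio of 2.02 ran from 0.98 at a minimum of 500 genes to 3.85 at a limit of 5% mitochondrial UMIs. Monocyte subset genes lay at -2.06 (percentile 0) with 11 of 12 lower, such as Chil3 at 4.89-fold, while Ly6c2 was 1.05-fold higher. The list mixes markers of classical monocytes, such as Ly6c2 and Chil3, with those of nonclassical monocytes, such as Cx3cr1. Its median therefore shows no shift between the subsets. DNA replication genes lay at -1.83 and G2M genes at -0.86, both at percentile 0, with 14 of 16 and 10 of 20 lower, such as Rrm2 at 8.42-fold and Top2a at 4.73-fold, but the DNA replication log2 ratio of -2.02 became -0.37 at halved or doubled clustering resolution. Secondary granule genes lay at -1.42 (percentile 0), with Lyz2 9.87-fold lower but Lcn2 at 8958 CPM against 88.4 CPM, 101-fold higher, and the list's log2 ratio of -1.62 became -0.04 with free RNA subtracted. Antioxidant and iron genes lay at 0.61 (97.2%), with ferritin Fth1 22.0-fold and heme oxygenase Hmox1 30.02-fold higher. Glycolysis lay at 1.01 (99.8%) with Pfkfb3 14.0-fold higher, and osteoclast genes at 2.88 (99.8%) with Acp5 7.96-fold higher. Efflux genes lay at 0.25 (73.1%), with Abca1 18.7-fold and Plin2 7.28-fold higher.

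Of 3499 genes of monocyte-like cells, 538 were higher and 647 lower, or 634 and 507 with TMM factors, under which the median of these genes moved from -0.17 to 0.02. All 115 cells of the null-labelled library were in sub-cluster 17, with Saa3, Hmox1, Ccl2 and Fcgr1 among its leading genes. Most of the 509 control-labelled cells were in 90, 108, 87, 109 and 110, of which 109 had Slfn5, Ifi204 and Ifi27l2a. The other 25 were in 111, with Ace, Eno3 and Ear2 of the monocyte subset list among its leading genes. The class thus compares different sub-clusters, and Cx3cr1 and the monocyte subset list are not read as differences within a monocyte subset.

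Mature B-like cells of the null-labelled library held more interferon and glycolysis transcripts and fewer transcripts of Fcer2a, the low-affinity IgE receptor, and Fcmr, the IgM receptor. At a limit of 5% mitochondrial UMIs the log2 ratio of their share fell to -5.45 and too few cells were left to compare. The values of this class therefore rest on the limit of 10%. Cxcl10 had 1234 UMIs against 0, at least 374-fold higher, and Fgl2 129 against 0, at least 39.1-fold higher. Iigp1 had a ratio of 396 over 1 control UMI (70.8 to 15689.8) and Gbp2 was 103-fold higher (62.0 to 184). Serpina3f, AA467197, Serpina3g, Ifit2, the perforin-like Mpeg1, Ifit3, Ifitm3 and Zbp1 were between 71.6-fold and 22.7-fold higher. Fcer2a was at 2.02 CPM against 216 CPM, 107-fold lower (45.6 to 331), and Fcmr at 44.8 CPM against 644 CPM, 14.4-fold lower (11.8 to 17.6). Il4i1 had 2 UMIs against 175, a ratio of 96.3 (26.3 to 801). Glycolysis genes lay at 1.12 relative to all genes (99.98%) with 6 of 12 higher, such as Pkm at 4.36-fold and Ldha at 3.51-fold. Light chain and B activation genes lay at 1.11 (99.8%), with Myc 10.1-fold higher and Cd72 7.002-fold lower, and ribosomal proteins at 0.56 (99.98%), with Rps2 3.31-fold higher. Integrins lay at -0.89 (0.820%) with 5 of 11 lower, such as Itgb7 at 8.41-fold, and immediate early genes at -0.79 (0.590%).

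Other genes low in the null-labelled mature B-like cells are known from other cells or from division. Lyz2 had 1 UMI against 148, a ratio of 163 (28.8 to 6474). The erythroid genes Alas2, Hbb-bt and Hbb-bs were 18.2-fold, 17.4-fold and 11.8-fold lower, Lgals1 16.9-fold and Cbfa2t3, a corepressor of several blood lineages, 20.3-fold. Hemoglobin lay at -3.42 (percentile 0) and made up 7.65% of UMIs summed over the control-labelled class but 0.287% in its median cell. G2M genes lay at -3.50 (percentile 0), with 18 of 19 lower, such as Ube2c at 37.7-fold and Cenpf at 30.6-fold, and their log2 ratio of -3.56 ran from -5.09 with free RNA subtracted to -0.85 without cell filter. The share of cycling cells after thinning was 3.38% and 3.95%, so no order in cycling is read. Of 3371 genes, 444 were higher and 510 lower, or 541 and 427 with TMM factors. Sub-clusters 29, 28 and 7 held the class in the null-labelled library, and 104, 72, 71 and 106 its largest parts in the control-labelled library. No control-labelled cell was in 29, 28 or 7. Fcer2a and Fcmr, which are naming markers of the class, were among the leading genes of the control-labelled sub-cluster 104. The class thus compares different sub-clusters, and neither gene is read as a difference within 1 type of B cell.

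B precursor-like cells of the null-labelled library held more interferon and MHC class II transcripts and fewer of DNA replication. Iigp1 was at 674 CPM against 1.01 CPM, 669.7-fold higher (286 to 2067), Serpina3g 91.0-fold, Gbp2 75.5-fold and Serpina3f 74.3-fold higher, and Gbp6 had a ratio of 295 over 1 UMI (51.7 to 11783). MHC class II genes were 2-fold higher in 8 of 8 cases and lay at 2.08 (100%), such as H2-Eb1 at 6.35-fold, H2-Aa at 5.55-fold and Cd74 at 3.599-fold. DNA replication genes lay at -0.79 (percentile 0) with 8 of 16 lower, such as Rrm2 at 3.74-fold and Lig1 at 2.5003-fold. Heat shock genes lay at -0.67 (0.5%) with Hspd1 5.21-fold lower, and light chain and B activation genes at -0.98 (0.170%) with Myc 9.22-fold and Bach2 3.04-fold lower, whose log2 ratio of -1.15 became -0.16 without doublet removal. Ms4a1, which encodes CD20, was 21.1-fold lower (8.15 to 78.0), the calcium channel Cacna1e 20.4-fold and Dnajc7 6.67-fold. Neutrophil genes were also lower, with Lyz2 at 14.2-fold and Retnlg at a ratio of 87.6 with 1 UMI (15.6 to 3472), and S100 genes at -2.41 (0.0100%). With free RNA subtracted the S100 value turned positive, but counts set to 0 can give such a ratio from the class totals. No change of sign is read from it.

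Of 3415 genes of B precursor-like cells, 222 were higher and 340 lower, or 272 and 245 with TMM factors, under which the median of these genes moved from -0.15 to 0.00. Sub-clusters 6 and 8, the latter with Serpina3f among its leading genes, held most of the class in the null-labelled library, and 45, 42 and 44 held most of it in the control-labelled library. Sub-cluster 5, with 148 null-labelled cells, scored for both B stages and was left without a stage, so later precursors were left out of 1 library more than the other, and differences in stage genes such as Ms4a1 are not read as differences within 1 stage.

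T-like cells of the null-labelled library held more interferon, NF-kB and glycolysis transcripts and fewer of the integrin list. Gzmb, the killing enzyme granzyme B, had 831 UMIs against 4, 151-fold higher (58.6 to 554). AA467197 had 342 UMIs against 0 and Calca 200 against 0, at least 82.7-fold and 48.3-fold higher, and Cxcl10 and the metallothionein Mt1 had ratios of 261 (46.6 to 10338) and 237 (42.3 to 9393) over 1 UMI each. NF-kB and cytokine genes lay at 1.21 (99.98%) with 4 of 8 higher, such as Cxcl2 at a ratio of 12.3 over 2 UMIs (3.16 to 106), Tnfaip3 at 3.98-fold and Nfkbia at 3.22-fold. Glycolysis lay at 0.93 (99.98%) with 4 of 10 higher, such as Pkm at 3.797-fold. Integrins lay at -1.40 (percentile 0) with 6 of 9 lower, such as Itgb7 at 9.48-fold, whereas Itgav was 6.92-fold higher (3.90 to 13.4). The lowest genes were erythroid, with Hbb-bt 67.7-fold, Hbb-bs 46.2-fold, Hba-a2 41.7-fold and Hba-a1 39.5-fold lower, and hemoglobin lay at -5.42 (percentile 0). Of 2928 genes, 311 were higher and 347 lower, or 361 and 303 with TMM factors. Sub-clusters 41, 39 and 40, of which 41 had Gzmb and Gzma and 39 had Gzmb among their leading genes, held most of the class in the null-labelled library, and 97, 96, with Ccl5 among its leading genes, and 99 did so in the control-labelled library. With NK cells as the second class, 41 and 39 scored 0.519 and 0.337, and 96 and 99 scored 0.36 and 0.223. The class thus compares different sub-clusters, and Gzmb is not read as a difference within 1 type of T cell.

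Cycling cells, those with 3 or more UMIs of the G2M list after thinning, were 30.6% of the null-labelled (28.9 to 32.3) and 37.0% of the control-labelled library (36.0 to 38.1). Unthinned, the order was the opposite, at 77.7% and 67.2%. Erythroid-like cells were counted so at 40.7% and 59.8%, and monocyte-like cells at 21.7% and 43.4%. The call leans on Hmgb2, an abundant member also present outside division, with 61545 and 137463 UMIs over all cells against 6577 and 25519 for Top2a. In mature neutrophil-like cells, at 10.7% and 22.0%, Hmgb2 had 1540 and 4607 UMIs and Top2a 22 and 18, the latter 2.69-fold higher in the null-labelled library, so division is not read in that class. T-like cells, mostly at rest, gave 3.01% and 2.97%. B precursor-like cells, at 51.0% and 30.6%, and immature neutrophil-like cells, at 52.2% and 42.8%, went against the G2M medians of -0.38 and -0.13, so no order is read for them.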

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

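The tests on a few abundant genes, on the Itgb3 ratio between HSPC-like and lymphoid cells, on hemoglobin in the median cell and in the T-cell sum, and on the genes near Itgb3 were chosen after the results were seen.

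Isg15 and Saa3 also differed between the libraries in barcodes under the cell filter, data on which nothing was reported. In the 1307 such barcodes of the null-labelled library, Isg15 was at 463 CPM (449.6 to 476), against 152 CPM (146 to 159) in the control-labelled library. Of 2 further interferon genes, Ifit1 was at 11.3 CPM (9.32 to 13.6) against 3.22 CPM (2.31 to 4.37), while Ifi27l2a was not higher, at 8.01 CPM (6.35 to 9.96) against 10.8 CPM (9.11 to 12.8). Saa3 in the same barcodes was at 71.6 CPM (66.5 to 77.1) against 0.157 CPM, the latter from 2 UMIs. Hemoglobin made up 91.7% and 88.6% of the UMIs of these barcodes, so most of their RNA was of red cells.

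The interferon genes were higher in the null-labelled library in each of the 7 classes compared. Free RNA of 1 source carried into every cell would give all classes the same mix of interferon genes, but every class differed in that mix from the rest of its library, by a multiple of the counting noise that was lowest in T-like cells, at 14.6. Free RNA was therefore excluded as the sole source of these UMIs. The mix does not decide how much of the difference came from free RNA, since classes can also differ in their own expression of the members. After free RNA was subtracted, at a pooled share of uncertain size, the lowest class median was 2.23. That value does not decide it either. The control-labelled share of 14.7% leans on summed hemoglobin that was not evenly spread in T-like cells, and subtracting too much there raises the ratio. A few abundant genes shifting the totals were excluded as well, since the lowest interferon median relative to all genes was 2.41. The Itgb3 genotype and the state or handling of the animals or library, an infection for example, cannot be told apart, because there was 1 library per genotype.

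Itgb3 transcripts were found in HSPC-like cells of the library labelled Itgb3 null. Their CPM was 5.27 times that of B-like and T-like cells of the same library, with a lower bound of 3.54, and 48 of their 70 UMIs lay in sub-cluster 23, which leans to the megakaryocyte, so free RNA spread evenly over all cells did not account for it. Reads from the 3′ end of a disrupted allele and transcripts of an intact allele cannot be told apart, because the 248 UMIs of this library are counts per gene without positions along it. No biological explanation was tested.

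Hemoglobin UMIs in lymphoid cells of the control-labelled library had more than 1 form. In the median cell, the highest over the lowest hemoglobin share among mature B-like, B precursor-like and T-like cells was 1.29, a near-even level that could come from free RNA. Summed over T-like cells, 97.2% of hemoglobin UMIs lay in the 21 cells with the most, while the same number of deepest cells held 20.2% of all UMIs, and evenly spread free RNA was excluded as the source of that sum. Doublets with erythroid cells stay open for the sum, because 43.6% of the T-like cells (36.6 to 50.7) held 3 or more hemoglobin UMIs after thinning, and such a share does not separate doublets from free RNA. Among mature B-like cells, the control-labelled sub-clusters 73 and 107, with 38 and 27 cells, had the erythroid class as their second, at 0.218 and 0.429. How much of the hemoglobin of the class they held was not tested. The lower hemoglobin of null-labelled mature B-like and T-like cells therefore stays without a settled explanation, and no biological one was tested.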

How the results depend on the processing

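Clustering and naming without the 106 genes that differed in 5 or more classes was chosen after the data were seen. No paired analysis was possible because there was 1 library per genotype.

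Over the alternatives, values behind the main answers stayed near the main value in 159 cases, moved in 32 and reversed in 1, and the other values did so in 490, 266 and 10 cases. A value counted as near within the 95% counting interval of the main one, and a number of genes within 1.5 times of it. The neutrophil share stayed lower in the null-labelled library under every alternative run, with a log2 ratio from -0.67 to -0.56. The interferon medians stayed positive in each class, from 1.99 to 2.89 in T-like, 2.88 to 3.46 in mature B-like, 3.37 to 4.08 in mature neutrophil-like, 3.45 to 4.15 in monocyte-like, 4.30 to 5.44 in erythroid-like, 4.12 to 5.90 in B precursor-like and 4.81 to 6.75 in immature neutrophil-like cells. The lowest class median, 2.38, moved to 1.99 at a limit of 5% mitochondrial UMIs and to 2.89 as a mean over cells. The highest, 4.93, moved to 5.40 at a minimum of 500 genes, 5.44 with TMM factors and 6.75 with free RNA subtracted, and the cause was not tested. With the 106 genes left out, 95.3% of cells had the same class, and 102 of 109 sub-clusters still drew 90% or more of their cells from 1 library.

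Some class shares moved. The erythroid log2 ratio of 0.49 was 0.21 without filter. The mature neutrophil value of -1.01 ran from -2.31 with thinning before clustering to -0.97 at halved resolution. The monocyte value of -0.58 was -0.25 at halved and at doubled resolution. The T-like value of 0.95 was 1.33 at a limit of 5% mitochondrial UMIs and 0.58 without doublet removal, and the B lineage value of 0.10 was -0.47 at that limit. At the same limit the mature B share reversed from 0.47 to -5.45 and the B precursor share from -1.29 to 0.28. The cause was not tested.

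The number of genes at 2-fold or more depended on the CPM minimum by construction, since fewer or more genes are counted. Without a minimum and at 200 CPM it was 4912 and 261 in erythroid-like, 2127 and 118 in immature neutrophil-like, 2193 and 267 in mature B-like, 2310 and 284 in mature neutrophil-like, 1754 and 139 in B precursor-like, 1174 and 154 in T-like and 2958 and 317 in monocyte-like cells. The 1194 erythroid genes were 780 without cell filter and 664 with TMM factors, the 462 immature neutrophil genes 841 without the 20 most abundant genes, the 562 B precursor genes 1191 at a limit of 5% mitochondrial UMIs and 997 with thinning before clustering, and the 658 T-cell genes 317 with that thinning. The cause of these was not tested. At a limit of 5% mitochondrial UMIs, mature B-like cells were too few for a count.

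Lists that reversed were mostly of genes from other cells. With free RNA subtracted, at pooled shares of 3.88% and 14.7% whose sources disagree, secondary granule genes and S100 genes of erythroid-like cells came to 0.57 each, platelet genes of immature neutrophil-like cells to 0.65 and S100 genes of B precursor-like cells to 1.53. Counts under 0 were set to 0 in that subtraction, and genes at 0 in both libraries take a ratio set by the class totals. Both erythroid lists came to the same value, so no change of sign is read from these lists. Without doublet removal, secondary granule and S100 genes of mature B-like cells came to 2.34 and 0.58. Hemoglobin came to 0.0490 in immature neutrophil-like cells at a minimum of 500 genes and to 0.64 in mature neutrophil-like cells thinned before clustering. Other lists moved without a change of sign. Platelet genes over all cells, at -3.43, came to -0.84 as a mean over cells and -0.69 with thinning before clustering, and those of erythroid-like cells, at -3.05, to -0.88 with free RNA subtracted. Hemoglobin ran from -15.42 to -1.26 in mature B-like and from -13.68 to -2.27 in T-like cells, and G2M genes of mature B-like cells from -5.09 to -0.85. The lowest hemoglobin values rest on null-labelled counts at or near 0 UMIs and are not read as sizes. MHC class II genes of monocyte-like cells ran from 0.98 to 3.85. In erythroid-like cells, TMM factors took DNA replication genes from -1.55 to -0.69. Secondary granule genes of monocyte-like cells, at -1.62, came to -0.04 with free RNA subtracted, and DNA replication genes, at -2.02, to -0.37 at halved and doubled resolution. Light chain and B activation genes of B precursor-like cells, at -1.15, came to -0.16 without doublet removal. The cause of the other moves was not tested.

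Itgb3 over all cells stayed lower under each alternative, but its log2 ratio of -1.67 was -0.65 as a mean over cells. Without the megakaryocyte-like cells it was 1.25-fold lower (1.08 to 1.47). The 13 such cells of the control-labelled library held 159719 UMIs at a median of 841, so a few deep cells weigh more in a sum than in a mean over cells. How much of the move this makes up was not tested. The cycling share, with a log2 ratio of -0.28, reversed to 0.21 without thinning, as cells of the deeper null-labelled library were then counted at full depth. Depth limits the rare classes and the genes with few UMIs, and thinning to 1000 UMIs leaves Itgb3 detectable in few cells.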

Other observations

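The test on genes near Itgb3 was chosen after the results were seen, as were the genes named here.

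Classes too small for a full comparison also had interferon medians above 0 in the null-labelled library. HSPC-like cells, 67 and 85 in number and mostly in different sub-clusters, had a median log2 ratio of 4.44 with 18 of 18 members higher, MHC class II genes at 3.39 with 4 of 6 higher and NF-kB genes at 1.81 with 7 of 10 higher. Their chemokine Ccl5 was at 9106 CPM against 0.818 CPM from 1 UMI (1998 to 439749), Cxcl10 had 7364 UMIs against 0, at least 1667-fold higher, and the stem cell marker Ly6a was 19.9-fold higher (14.7 to 27.5). Ly6a was also higher in NK-like cells, at 53.0-fold (14.4 to 443), and in granulocyte-monocyte progenitor-like cells, at 36.5-fold (18.1 to 86.0). It was 2.40-fold higher in plasmacytoid dendritic-like cells, and in plasma-like cells its interval spanned 1 (0.598 to 5.66). Its higher value is therefore not read as one of stem cells. Granulocyte-monocyte progenitor-like cells had interferon genes at 5.86 with 18 of 18 higher and NF-kB genes at 3.41 with 12 of 13 higher. Mpo, the granule peroxidase, was 2.85-fold lower in them (2.77 to 2.92). Of their null-labelled cells, 36 lay in sub-cluster 15 and 62 in 19. The control-labelled cells lay in 63, 64, 65 and 89, so Mpo is not compared within 1 stage. Plasmacytoid dendritic-like cells had interferon genes at 4.84 but MHC class II genes at -0.82, and basophil or mast-like cells 10 of 10 interferon genes higher at 3.92. NK-like cells had an interferon median of 0.85 with 2 of 6 genes higher, and Gzmb was 4.36-fold higher (3.26 to 5.94). The NK-like cells lay in different sub-clusters, 38 in the null-labelled and 98 in the control-labelled library.

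Macrophage-like cells, 46 and 110 in number with median depths of 926 and 3450.5 UMIs, lay in different sub-clusters, all null-labelled cells in 18 and all control-labelled cells in 85 and 86, which had the erythroid class as their second, so the values compare sub-clusters. Interferon genes were at 2.80 with 13 of 16 higher and NF-kB genes at 3.19 with 6 of 6 higher, while G2M genes were at -3.83 with 13 of 13 lower and DNA replication genes at -3.32 with 11 of 11 lower. Ccl8 was 35.1-fold higher and Ubd 15.9-fold. Vcam1, an adhesion molecule of resident macrophages, was 10.99-fold lower (7.16 to 17.8), and Slc40a1, the iron exporter ferroportin, had 0 UMIs against 666. Among the few stromal or endothelial-like cells, 11 and 10, the interferon median was 3.43 with 7 of 8 higher, and Il6 had 73 UMIs against 0, at least 27.2-fold higher. Ifng, which encodes interferon gamma, was at 54.4 CPM (41.4 to 70.2) against 19.1 CPM (10.7 to 31.5) in T-like cells, and in NK-like cells its ratio of 0.676 had an interval that spanned 1 (0.311 to 1.44). Among the 28 plasma-like cells of the null-labelled library, the 14626 Igha UMIs came from 4 cells and the 12420 Jchain UMIs from 8.

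Genes next to Itgb3 were examined for a flank of donor-strain chromosome around the targeted allele, which could move many neighbours. Of 38 measured genes within 5 Mb, 8 were 2-fold different (21.1%), against 18.1% of all measured genes, and this share was at percentile 63.9 of 2470 overlapping windows elsewhere. No excess of 2-fold genes was thus seen near Itgb3. A flank that moved a few genes, or moved genes by under 2-fold, is not excluded by this share. Among the 8 were the interferon-related genes Dhx58, with a median log2 ratio over classes of 3.06, Stat3 and Ifi35, at 1.42 and 1.33, and Gna13, at 1.67. Gna13, which encodes a G protein subunit (ENSMUSG00000020611, chromosome 11 from 109362831 to 109401369), was higher in each of the 7 classes, with a log2 ratio from 1.46 in mature B-like to 3.56 in monocyte-like cells, and was at 203 CPM against 47.9 CPM over all cells.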
